A study of Mus musculus with 4 samples.

How the data were processed

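RNA of sorted CD4+ CD8- mouse thymocytes was analysed on Affymetrix mouse 430 2.0 arrays. Per the labels' protocols, RNA was extracted on columns, converted to biotin-labelled cRNA with 2 rounds of amplification and hybridised to the arrays. Rounds of amplification shorten products from their 5' ends, so a probe set far from the 3' end of a transcript can lose signal to a different degree on each array. The groups were taken from the sample titles: GFP- CD25-, GFP- CD25+ and GFP+ cells of Foxp3(gfp/gfp) mice and GFP+ cells of Foxp3(gfpko/wt) mice. The description of the last sample repeats the text of the gfp/gfp mice, so its group rests on its title and on its strain entry, which differs. Each group had 1 array, and 4 value columns were used. No column was left out.

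The deposited table holds 1 value per probe set and array, on a scale that the values show to be logarithmic and that was taken as log2. The authors' method of background correction, summarisation and normalization is not given in the sources used here, and the log base is inferred from the range of values. On this scale array means lay within 0.06 of each other, whereas 90th percentiles ran from 7.54 to 8.17. The arrays were therefore not on a common scale at high signals, and by the rule fixed beforehand the log2 values were quantile normalized for the main results. That choice was made before any difference between arrays was counted. Quantile normalization assumes that the arrays have the same distribution of signals. The values as deposited were kept as an alternative, and the split of higher and lower genes is given on both scales.

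Of 45101 probe sets, 64 control probe sets were left out. A gene name came from the platform annotation for 34970 probe sets with 1 gene; 920 probe sets had several genes and 9211 had none listed, and neither was named. Symbols were updated through gene identifiers in the RefSeq table of assembly GRCm38.p6, which held 34754 of the 34970, and 12 symbols changed. That table was used only for names, chromosomes and overlapping neighbours. Each of the 18201 genes was represented by the probe set with the highest mean over the 4 arrays; 9014 genes had more than 1. The floor was the highest of the 4 arrays' 90th percentiles over probe sets of silent tissue genes, 4.25 log2 (4.30 on the deposited scale). Lower values were set to the floor. A difference with 1 side at the floor is a lower bound, written "at least", and none is given with both sides at the floor.

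With 1 array per group no significance test was made. A gene was counted when 2 arrays differed by at least 2-fold. The 6 comparisons were all pairs of arrays, and fold values are ratios of the normalized signals. The text names Foxp3 first, then the 10 largest differences in each direction per comparison, and any member of a fixed list. Transcripts without a gene name and receptor or immunoglobulin gene segments were skipped, 7 in all. Of the genes 2-fold apart, those with a second probe set above the floor were checked on it for direction.

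Before the data were examined, 26 gene lists were fixed. They cover regulatory T cell genes, genes low in regulatory T cells, the T cell receptor signal response, the NF-kappaB and TNF receptor family, effector cytokines, T helper transcription factors, trafficking and adhesion, immature thymocytes, mature single-positive thymocytes, the cell cycle, apoptosis regulators and signal attenuators. Glycolysis, cholesterol synthesis, ribosomal proteins, interferon-stimulated genes, and dissociation and heat shock stress were also listed. Markers of B cells, dendritic cells and macrophages, NK and NKT cells, CD8 T cells, gamma delta T cells, thymic epithelium and erythroid cells served to look for other cells, with silent tissue genes for the floor and 2 strain marker genes. Some genes stand in more than 1 list. For each list with at least 5 measured members, the median log2 difference was placed among the medians of 10000 random gene lists of the same size, matched on mean expression in 20 bins. The range of the central 95% of these medians describes these arrays and is no test of the conditions.

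Overlaps and correlations between comparisons that share an array were set beside 100 simulated sets of unchanged arrays and beside independent lists, and correlations were also taken between comparisons with no shared array. The alternatives were the deposited scale, centring each array on the median of probe sets above the floor, no floor, a floor at each array's median, a floor 1 log2 unit higher, the median over the probe sets of a gene, leaving out probe sets that can match several transcripts, and thresholds of 3-fold and 1.5-fold. Leaving the sort genes out of the lists was added after the data were seen. A value was counted as moved when it differed by more than 1.5-fold from the main one, or for a correlation or covariance by at least 0.1.

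The scripts were tested on simulated data for Foxp3-fusion over GFP- CD25- cells, with noise of 0.3 log2 (SD) and 200 of 18201 genes changed. They recovered 80.6% of 67 genes with a change of 1.5 log2, 100.0% of 63 with 2.0 and 100.0% of 69 with 3.0. Of 7873 unchanged genes, 102 (1.30%) passed 2-fold. That share holds for the noise set here and is no error rate of the real arrays. The unchanged arrays simulated for the overlaps had a higher median noise, 0.39 log2 (SD), at which more unchanged genes pass. Of 100 simulated unchanged lists of 20 genes, 2 lay outside the random range, and 100 of 100 lists shifted by 0.5 log2 lay above it. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The detection limit set by the floor, the single array per group and the 3' bias are the main limits of these measurements, and no depth is defined for array signals.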

Results

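Gene expression was measured in 4 populations of mouse CD4+ CD8- thymocytes with Affymetrix mouse 430 2.0 arrays, 1 array per population. Females of 6 to 8 weeks were used, and cells were sorted by magnetic beads and then by flow cytometry. Foxp3 encodes the X-linked transcription factor that marks regulatory T cells. Reporter mice homozygous for an allele that makes a GFP-Foxp3 fusion protein gave GFP- CD25- cells, GFP- CD25+ cells and GFP+ cells, the last called Foxp3-fusion cells here. Females heterozygous for a GFP-tagged knockout allele gave GFP+ cells that use the Foxp3 locus from that allele, called Foxp3-null cells here. The mice of the Foxp3-null array had been backcrossed to C57BL/6 for 2 generations, and those of the other 3 arrays for 4 to 6 generations. Genotype, mice and array are therefore confounded in each comparison with Foxp3-null cells. Every difference is between 1 array and another, has no replicate check, and carries no p-value or error. The number of arrays limits the precision of every value.

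Of 18201 genes on the array, 8420 were above the floor of 4.25 log2 in at least 1 population and 7016 in all 4. The number above the floor was 7550 in GFP- CD25- cells, 7640 in GFP- CD25+ cells, 7799 in Foxp3-null cells and 7598 in Foxp3-fusion cells. Signals correlated across probe sets between arrays with Pearson's r from 0.964 to 0.983, where probe sets are not independent replicates. The actin control probe sets for the 3' and 5' ends differed by 8.37 log2 on the GFP- CD25- array, 9.29 on the GFP- CD25+ array, 7.10 on the Foxp3-null array and 5.02 on the Foxp3-fusion array. For Gapdh the same gaps were 6.56, 6.51, 4.93 and 4.60. The bioB hybridisation spike read 9.26, 10.09, 11.25 and 8.07 log2 in that order.

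Foxp3 signal was at the floor in both GFP- populations and well above it in both GFP+ populations. The log2 values were 2.76 in GFP- CD25- cells, 2.88 in GFP- CD25+ cells, 7.27 in Foxp3-null cells and 8.82 in Foxp3-fusion cells. Foxp3 was thus at least 23.9-fold higher in Foxp3-fusion cells and at least 8.12-fold higher in Foxp3-null cells than in GFP- CD25- cells. Foxp3-fusion cells exceeded Foxp3-null cells by 2.94-fold, and by 4.67-fold on the deposited scale. Whether the single Foxp3 probe set lies in the part removed from the knockout allele is not given in the sources used here, so its level does not check the null label. The annotated span of Foxp3 overlaps that of Ccdc22 in GRCm38.p6, and the Ccdc22 signal ran the other way, at 8.28, 9.25, 7.23 and 5.70 log2 over the same 4 arrays. Foxp3, through GFP, was used in the sort, as were Cd4 and Cd8a, so their levels are not findings. Il2ra, which encodes CD25, was used to split the GFP- cells, so its level there and any difference from those cells is not a finding. The titles name no CD25 gate for the GFP+ cells. Among them Il2ra was 2.37-fold higher in Foxp3-fusion than in Foxp3-null cells, or 1.82 log2 on the deposited scale. The other Il2ra probe set read 2.76, 5.27, 3.77 and 6.42 log2 over the 4 arrays in the order above. On it Foxp3-null cells were under the floor and below GFP- CD25+ cells, the reverse of the probe set used (9.11 against 7.85).

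Foxp3-fusion cells were compared with GFP- CD25- cells to describe regulatory T cells among CD4 thymocytes of the same kind of mice. Genes known from regulatory T cells led the difference. Ctla4, an inhibitory receptor, was 180.1-fold higher in Foxp3-fusion cells. Rgs1, which damps signals from G protein-coupled receptors, was 85.9-fold higher, and Itgae, the CD103 integrin chain, was 35.9-fold higher. Itgb8, an integrin chain involved in activating TGF-beta, was at least 71.3-fold higher, and the chemokine receptor gene Ccr6 was at least 61.4-fold higher. Sema4a, a semaphorin, was 38.5-fold lower, and Pde3b, which breaks down cyclic AMP, was 32.1-fold lower.

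Others among the 10 largest differences upward were the zinc finger gene Plagl1 at 44.7-fold, Cd83 at no less than 34.8-fold and the MAP kinase phosphatase gene Dusp4 at no less than 27.8-fold. Il2ra, by which the GFP- CD25- cells were sorted, was at least 68.8-fold higher. Downward, the list continued with Igfbp4 at 20.7-fold, Marcks at 20.5-fold, the transcriptional inhibitor gene Id2 at 17.6-fold and the chemokine receptor gene Ccr9 at 17.6-fold. Enc1 was 17.1-fold lower, Phxr4 14.3-fold, Psg28 13.6-fold and Pxylp1 at least 13.1-fold.

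Of 26 measured regulatory T cell genes, 24 were at least 2-fold higher in Foxp3-fusion cells and 0 were at least 2-fold lower. Their median log2 difference was 2.92, against -0.22 to 0.28 for random lists of matched expression (their central 95%, used in the same way below). The list holds the sort gene Il2ra; without it 23 of 25 were higher and the median was 2.89. In the comparisons that follow, leaving out Il2ra, a choice made after the data were seen, gave medians of 2.07, 1.26, 1.49, 1.45 and 0.52 in place of 2.14, 1.25, 1.54, 1.46 and 0.54. Nrp1 was 12.8-fold higher, Tnfrsf4 10.2-fold, Ikzf2, which encodes Helios, 4.16-fold, and Il2rb at least 10.2-fold. Genes known to be low in regulatory T cells had a median of -1.03 (random lists, -0.47 to 0.49), with 6 of 11 at least 2-fold lower, among them Satb1 at 4.94-fold and Il7r at 2.46-fold, while Ccr7 was 2.04-fold higher. Among genes of the NF-kappaB and TNF receptor family, 7 of 17 were at least 2-fold higher and 0 lower, with a median of 0.87 (random lists, -0.31 to 0.40) and Tnfrsf1b at 12.3-fold. Tnfrsf4, Tnfrsf9, Tnfrsf18 and Cd83 are among them and also stand in the regulatory T cell list, so these lists are not independent. The same genes were at least 2-fold higher than in GFP- CD25- cells in Foxp3-null and GFP- CD25+ cells. In the trafficking and adhesion list, 7 of 17 genes were at least 2-fold higher and 2 lower, with a median of 0.85 (random lists, -0.28 to 0.38). Itgb1 was 7.35-fold higher and Cd44 3.69-fold, whereas Itga4 was 3.63-fold lower.

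Immature thymocyte genes had a median of -1.07 in Foxp3-fusion over GFP- CD25- cells (random lists, -0.41 to 0.44), with 6 of 11 at least 2-fold lower and 0 higher. Cd24a was 5.84-fold lower and Sox4 3.77-fold lower. Ribosomal protein genes had a median of 0.92 (random lists, -0.53 to 0.26), with 6 of 13 at least 2-fold higher, such as Rpl7 at 2.74-fold. The actin 3' to 5' gap was smaller on the Foxp3-fusion array by the values given above. Signal attenuators moved both ways, with 7 of 17 at least 2-fold higher and 4 lower. Socs2 was 17.5-fold higher and Cish, another cytokine-signal inhibitor, 8.17-fold, whereas Dusp6 was 3.59-fold lower. Other single differences included Pim1, a survival kinase gene, at 15.8-fold higher, Ahr at 10.4-fold higher and Gbp3 at 13.1-fold higher. Cell cycle genes had a median of 0.03, inside their random range of -0.25 to 0.32.

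In this comparison 801 genes were at least 2-fold higher and 430 at least 2-fold lower of 7867 measured, so 65.1% of those 2-fold apart were higher. On the deposited scale, without quantile normalization, the split was 1156 higher and 290 lower, or 79.9% higher, and the median over all measured genes went from -0.05 to 0.13. Among genes with another probe set above the floor, called bright in these checks, that probe set went the same way for 73.5% of 272 higher genes and 78.8% of 222 lower genes. Unrelated probe sets would also go the same way for many genes, so such shares alone are a weak check. It reached 2-fold that way for 40.1% and 23.9%, and 2-fold the opposite way for 5 and 10 genes. Of 102 list genes 2-fold apart, 4 were under 2-fold on the deposited scale.

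**Figure D1:**
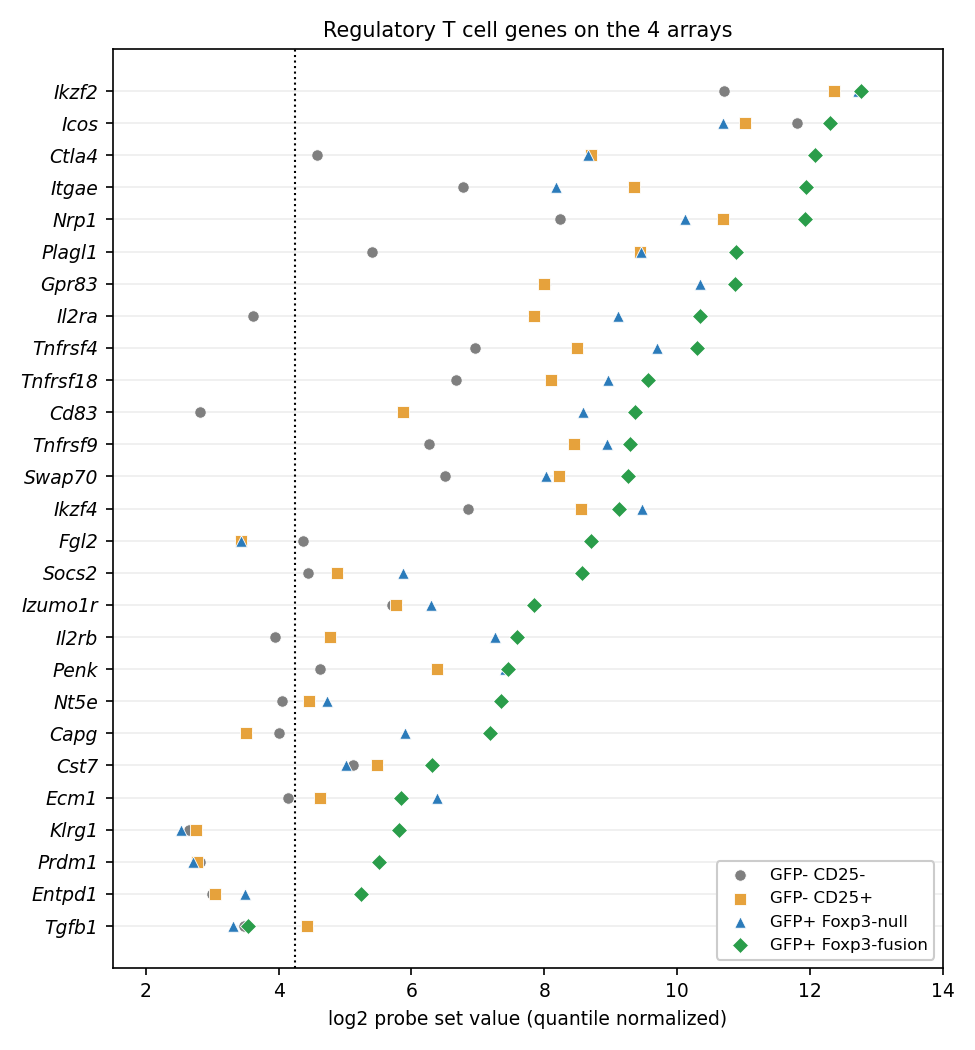
Signals of the regulatory T cell genes on the 4 arrays, 1 symbol per array, as quantile-normalized log2 probe set values; the dotted line is the floor of 4.25 log2. Ctla4 lay at 4.58 in GFP- CD25- cells, 8.70 in GFP- CD25+ cells, 8.65 in Foxp3-null cells and 12.08 in Foxp3-fusion cells, and Ikzf2 had nearly the same value in both GFP+ populations (0.05 log2 apart).

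Foxp3-null cells were compared with GFP- CD25- cells to ask which differences accompany use of the Foxp3 locus when it makes no Foxp3 protein. Part of the regulatory T cell pattern was present in them. Itgb8 was at least 38.1-fold higher, Ccr6 at least 35.4-fold, Cd83 at least 20.1-fold, Rgs1 19.9-fold and Ctla4 16.8-fold. Mid1, a ubiquitin ligase gene, was at least 81.1-fold lower in Foxp3-null cells, the largest difference downward. It read 10.59 log2 in GFP- CD25- cells and lay under the floor in Foxp3-null cells.

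The next genes upward were Pla2g4f at no less than 25.1-fold, the glutathione transferase gene Gsta4 at no less than 23.3-fold, the netrin gene Ntn4 at 22.2-fold and the prostaglandin receptor gene Ptger2 at 17.5-fold. Il2ra, by which the GFP- CD25- cells were sorted, was at least 29.1-fold higher on the probe set used. Its other probe set was under the floor in both populations. Downward, Chdh was 21.2-fold lower, Ncbp3 at least 17.6-fold, the cytokine receptor gene Il17rb at least 13.5-fold and Tbc1d23 at least 12.9-fold. Phxr4 was 12.1-fold lower, Inpp4b 11.4-fold, Rpf1 11.2-fold, Amn1 at least 11.05-fold and Pxylp1 11.02-fold.

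Of 23 measured regulatory T cell genes, 18 were at least 2-fold higher in Foxp3-null cells and 1, Icos, was at least 2-fold lower. The median was 2.14 (random lists, -0.11 to 0.47). Ikzf4 was 6.13-fold higher, Penk 6.93-fold, Gpr83 5.05-fold and Tnfrsf18 4.88-fold. Icos was 2.17-fold lower. The NF-kappaB and TNF receptor list had a median of 1.02 (random lists, -0.21 to 0.56), with 8 of 16 at least 2-fold higher and 0 lower, including Tnfrsf1b at 7.51-fold and Nfkb2 at 4.93-fold. Genes low in regulatory T cells had a median of -0.14, inside the random range of -0.38 to 0.59, although Igfbp4 was 4.64-fold lower and Il7r 3.54-fold lower. Immature thymocyte genes had a median of -1.07 (random lists, -0.36 to 0.59), with 7 of 11 at least 2-fold lower and 0 higher, among them Ccr9 at 5.85-fold and Tox at 2.43-fold.

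Cell cycle genes stood out in Foxp3-null cells. Over GFP- CD25- cells, 12 of 21 were at least 2-fold higher and 0 lower, with a median of 1.12 (random lists, -0.08 to 0.49). Mki67 was 4.42-fold higher, the cyclin gene Ccne1 4.06-fold, Top2a 3.81-fold and Pcna 3.63-fold. The median was 0.81 with deposited values, with 8 at least 2-fold higher and 1 lower, and 0.40 with the median over the probe sets of each gene. Ribosomal protein genes had a median of 0.67 (random lists, -0.40 to 0.38), with 2 of 13 at least 2-fold higher, and 0.44 with 0 higher on the deposited scale. T cell receptor response genes had a median of -0.23, just under their random range of -0.22 to 0.52, with 3 of 16 at least 2-fold higher and 1 lower; deposited values gave -0.51, with 2 higher and 3 lower. Nr4a3 was 5.89-fold higher, Pdcd1, which encodes PD-1, 4.87-fold higher, and Nfatc1 2.20-fold lower.

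In Foxp3-null over GFP- CD25- cells 870 genes were at least 2-fold higher and 611 lower of 8070 measured, or 58.7% higher. The deposited scale gave 430 higher and 945 lower, or 31.3% higher, and moved the median over all genes from 0.20 to 0.00. Another bright probe set went the same way for 77.2% of 281 higher genes and 61.5% of 335 lower genes, reached 2-fold that way for 27.8% and 22.4%, and 2-fold the opposite way for 14 and 9 genes. Of 87 list genes 2-fold apart, 19 were under 2-fold on the deposited scale.

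The comparison of Foxp3-fusion with Foxp3-null cells addresses the subject of the series, the effect of Foxp3 in cells that use its locus. Further expression of regulatory T cell genes was found in Foxp3-fusion cells. Fgl2, a secreted protein gene of regulatory T cells, was at least 21.9-fold higher, Itgae 13.5-fold, Ctla4 10.7-fold, Socs2 6.48-fold and Nt5e, the CD73 gene, 6.17-fold. Pde3b was 39.3-fold lower than in Foxp3-null cells, which were close to GFP- CD25- cells for this gene (0.30 log2 apart). Mid1 led upward at no less than 40.4-fold, with a signal under the floor on the Foxp3-null array.

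Slc35d1, a nucleotide sugar transporter gene, was 31.1-fold higher in Foxp3-fusion than in Foxp3-null cells, Tent5a at least 24.0-fold and the histone deacetylase gene Hdac9 at least 16.2-fold. Ccndbp1 was at least 12.8-fold higher, P4ha1 at least 12.2-fold, S100a4 at least 11.6-fold and Ncoa4 10.8-fold. Downward, Vat1 was 10.5-fold lower, but its difference was 0.00 log2 when the median over its probe sets was used. Nrp2 was 7.93-fold lower, Prr5l at least 7.69-fold, Tdrp 7.39-fold, Gpd2 7.26-fold and Dtx1, a regulator of Notch signalling, 6.37-fold. Kctd14 was at least 6.30-fold lower, Lmo4 6.00-fold and Lce1d 5.84-fold.

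Of 26 measured regulatory T cell genes, 15 were at least 2-fold higher in Foxp3-fusion than in Foxp3-null cells and 0 were at least 2-fold lower. The median was 1.25 (random lists, -0.41 to 0.17). The 11 genes under 2-fold apart included Ikzf2 at 0.05 log2, Penk at 0.04, Tnfrsf9 at 0.34, Tnfrsf4 at 0.60 and Ikzf4 at -0.35. These small differences depend on the scaling. On the deposited scale they were 0.59, 0.70, 0.96, 1.15 and 0.24 in that order, and 20 of the 26 genes were at least 2-fold higher. Genes low in regulatory T cells had a median of -0.68 (random lists, -0.57 to 0.38), with 5 of 11 at least 2-fold lower, including Igfbp4 at 4.47-fold and Dapl1 at 3.18-fold. With deposited values the median was -0.11, with 3 at least 2-fold lower and 2 higher. The NF-kappaB and TNF receptor list had a median of 0.34 (random lists, -0.57 to 0.27), with 0 of 17 at least 2-fold higher and 1, Nfkb2, 5.78-fold lower. With deposited values the median was 0.92, with 7 at least 2-fold higher and 1 lower. In the T helper transcription factor list, Maf was 3.94-fold higher, Rora 3.44-fold and Stat4 at least 5.82-fold, while the list median of -0.12 lay inside its random range of -0.55 to 0.26.

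Cell cycle genes were lower in Foxp3-fusion than in Foxp3-null cells, with 9 of 22 at least 2-fold lower and 0 higher. The median was -0.72 (random lists, -0.45 to 0.21), with Tpx2 4.04-fold lower, Ccne1 3.97-fold and Top2a 3.69-fold. On the deposited scale the median was -0.16, with 4 at least 2-fold lower and 0 higher. Immature thymocyte genes also had a median below their random range, -0.73 (random lists, -0.60 to 0.41), with 2 of 10 at least 2-fold lower and 1 higher, against -0.22, 0 and 3 on the deposited scale. So did dendritic cell and macrophage markers, at -0.97 (random lists, -0.75 to 0.42), with 3 of 7 at least 2-fold lower and 0 higher, against -0.81, 2 and 1 on the deposited scale. The trafficking and adhesion list had a median of -0.09 (0.52 with deposited values), inside its random range of -0.52 to 0.27, with 5 of 17 at least 2-fold higher and 4 lower. Itgb1 was 6.42-fold higher, Cd44 4.89-fold and Cxcr3 4.02-fold, whereas Ccr2 was 3.30-fold lower and Ccr9 3.01-fold lower. T cell receptor response genes had a median of 0.29 (random lists, -0.50 to 0.28), with 4 of 17 at least 2-fold higher and 3 lower. Nfatc1 was 4.62-fold higher and Irf4 3.54-fold, whereas Bcl2l11, which encodes the death protein Bim, was 2.502-fold lower. That median became -0.12 when arrays were centred on the median of the bright probe sets and -0.33 with a floor 1 log2 unit higher. With deposited values it was 0.61, with 5 genes at least 2-fold higher and 0 lower, so none of the lower calls held there.

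In Foxp3-fusion over Foxp3-null cells 762 genes were at least 2-fold higher and 753 lower of 8223 measured, or 50.3% higher. With the deposited scale the counts were 1617 higher and 294 lower, or 84.6% higher, and the median over all genes moved from -0.16 to 0.24. Of 246 genes in the fixed lists, 108 differed by over 1.5-fold between the scales and 54 had the opposite sign. Among the 75 list genes 2-fold apart, 19 were under 2-fold on the deposited scale and 0 had the opposite sign. In each of the other 5 comparisons 0 list genes differed by over 1.5-fold between the scales. Another bright probe set went the same way for 68.1% of 329 higher genes and 77.7% of 269 lower genes, reached 2-fold that way for 28.0% and 23.05%, and 2-fold the opposite way for 12 and 7 genes.

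Differences over GFP- CD25- cells were then set side by side. Of the 801 genes higher in Foxp3-fusion cells, among them Ctla4, Rgs1, Itgb8 and Ccr6, 302 (37.7%) were also at least 2-fold higher in Foxp3-null cells, and 97 were higher in both and in GFP- CD25+ cells. On the deposited scale 219 of 1156 higher genes were shared with Foxp3-null cells, a smaller share. The count of 97 was 64 with the median over the probe sets of each gene. Unchanged groups simulated against the same GFP- CD25- array shared 87.2 genes on average and 124 at most, and independent lists of the same sizes would share 82.8. For lower genes, such as Sema4a, Ccr9 and Igfbp4, 215 of 430 (50.0%) were shared, against 88.8 in simulation and 31.2 for independent lists. With the median over the probe sets of each gene 103 were shared, and on the deposited scale 206 of 290, a larger share. The simulated lists of higher genes were shorter: 205.7 genes on average were higher in Foxp3-fusion cells only of the 3 populations, against 475 observed. Longer lists that share an array overlap more, so 87.2 is no expected overlap for lists as long as the real ones. Part or all of either excess may come from the shared array. Across genes, which are not independent replicates, the log2 differences of the 2 GFP+ populations over GFP- CD25- cells correlated at 0.485, and simulation of no effect gave 0.501. Their covariance was 0.302 against 0.154 in simulation, a difference of 0.148, and with no floor the covariance was 0.15. With no array shared, Foxp3-fusion over GFP- CD25- correlated with Foxp3-null over GFP- CD25+ at 0.283, and Foxp3-fusion over GFP- CD25+ with Foxp3-null over GFP- CD25- at 0.124, with simulated values of 0.00 for both. Both GFP+ arrays had smaller actin and Gapdh 3' to 5' gaps than both GFP- arrays. A difference of that kind could also raise these correlations, and was not tested. Foxp3-fusion over Foxp3-null correlated with GFP- CD25+ over GFP- CD25- at -0.173, against 0.00 in simulation.

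**Figure D2:**
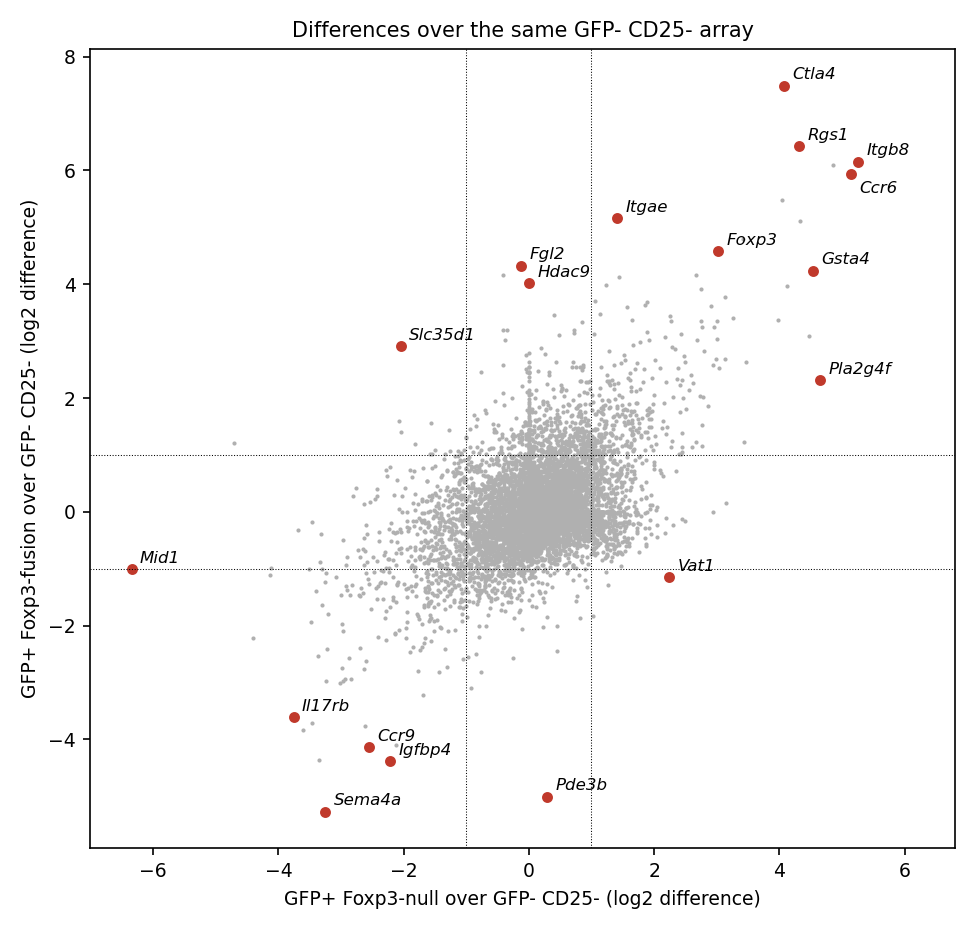
Log2 difference of each gene over GFP- CD25- cells in Foxp3-null cells (x axis) and Foxp3-fusion cells (y axis), 1 point per gene, for 8420 genes. A gene with 1 side at the floor is drawn at its bound, one with both sides at the floor at 0, and dotted lines mark 2-fold. Ctla4 lay at 4.07 and 7.49, Pde3b at 0.30 and -5.00, and Mid1 at -6.34 and -1.01.

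Set against Foxp3-null cells as well, 330 of the 801 genes higher in Foxp3-fusion than in GFP- CD25- cells (41.2%) were at least 2-fold higher, Itgae, Fgl2, Hdac9 and Socs2 among them. Simulation of no effect gave 88.1 such genes, and the deposited scale gave 725. The simulated lists were shorter than 801, so 88.1 is no expected count for a list of that size. Of the 430 lower genes 104 were also lower than in Foxp3-null cells, inside the simulated values, which reached 114. This count of 104 was 36 on the deposited scale, and 36 with the median over the probe sets of each gene. A set of 287 genes was at least 2-fold higher in Foxp3-fusion cells than in each of the 3 other populations, and 77 were at least 2-fold lower than in each. On the deposited scale these counts were 654 and 19. After quantile normalization the counts were 154 and 212 for Foxp3-null cells, 87 and 97 for GFP- CD25- cells, and 84 and 119 for GFP- CD25+ cells. Simulated unchanged arrays gave 37.4 higher and 37.0 lower on average for the Foxp3-fusion array after quantile normalization, and the deposited scale was not simulated. The simulated arrays had fewer higher genes 2-fold apart than the real ones, so these averages do not show how many genes noise supplied.

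GFP- CD25+ cells were compared with GFP- CD25- cells to describe CD25 status among cells without GFP-Foxp3. Several regulatory T cell genes were higher in the CD25+ cells although Foxp3 was at the floor in both. Ctla4 was 17.4-fold higher, Plagl1 16.5-fold, Rgs1 13.7-fold, Ptger2 12.4-fold and Itgb8 at least 22.1-fold. Igfbp4 was 29.9-fold lower, and Il7r, the interleukin 7 receptor gene, was 8.09-fold lower. Dntt, which encodes terminal transferase, was 8.28-fold higher.

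Rgs16 was 11.8-fold higher in GFP- CD25+ than in GFP- CD25- cells, Rapgef3 10.5-fold, Pla2g4f at least 9.504-fold and Dusp4 at least 8.49-fold, and Il2ra, a sort gene, at least 12.2-fold. Downward, the kinase gene Sgk1 was 11.8-fold lower, Pxylp1 10.8-fold, Fgd3 10.6-fold and Commd4 at least 9.93-fold. Klra16 was at least 9.33-fold lower, Edaradd 8.49-fold, Tmbim6 8.44-fold and Klhl4 at least 7.83-fold.

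Of 23 measured regulatory T cell genes, 13 were at least 2-fold higher in GFP- CD25+ cells and 0 lower, with a median of 1.54 (random lists, -0.13 to 0.28). Itgae was 6.00-fold higher, Nrp1 5.50-fold and Ikzf2 3.14-fold. The NF-kappaB and TNF receptor list had a median of 0.56 (random lists, -0.20 to 0.34), with 7 of 16 at least 2-fold higher. Mature single-positive thymocyte genes had a median of -0.65 (random lists, -0.27 to 0.37), with 3 of 13 at least 2-fold lower and 0 higher, such as Slfn1 at 2.92-fold. Interferon-stimulated genes had a median of -0.39 (random lists, -0.14 to 0.31), with 1 of 18, Ifit1, at least 2-fold lower and 0 higher. Genes low in regulatory T cells had a median of -0.60 (random lists, -0.30 to 0.41), but Bcl6 was 2.82-fold higher. The trafficking and adhesion list had a median of -0.33 (random lists, -0.22 to 0.32), although Ccr6 was at least 5.55-fold higher. T helper transcription factors had a median of -0.38 (random lists, -0.20 to 0.36), which became 0.07 with the median over the probe sets of each gene, and Ahr was 4.79-fold higher. The immature thymocyte list had a median of 0.02, inside its random range of -0.19 to 0.35, with 3 of 13 at least 2-fold higher and 2 lower, or 3 and 4 on the deposited scale. Arpp21 was at least 4.60-fold higher and Cd24a 2.81-fold higher, whereas Ccr9 was 4.28-fold lower. Cell cycle genes had a median of 0.32 (random lists, -0.13 to 0.30), with Mki67 2.22-fold higher, but 0.14 with deposited values, where 0 members were 2-fold apart and Mki67 differed by 0.91 log2. Cholesterol synthesis genes had a median of 0.44 (random lists, -0.28 to 0.43), with Insig1 2.69-fold higher.

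In GFP- CD25+ over GFP- CD25- cells 327 genes were at least 2-fold higher and 354 lower of 7856 measured, or 48.0% higher. Deposited values gave 214 higher and 567 lower, or 27.4% higher, and moved the median over all genes from 0.10 to -0.01. Another bright probe set went the same way for 88.5% of 131 higher genes and 70.8% of 137 lower genes, reached 2-fold that way for 31.3% and 21.2%, and 2-fold the opposite way for 0 and 0 genes. Of 60 list genes 2-fold apart, 6 were under 2-fold on the deposited scale. In simulated unchanged arrays, 205.7 genes on average were at least 2-fold above GFP- CD25- cells in Foxp3-fusion cells and in neither other population. For lower genes the average was 203.6. These averages leave out genes shared with another population, so the simulated counts between 2 arrays are higher still. Noise of the simulated size may therefore supply a large part or all of counts as small as those of GFP- CD25+ over GFP- CD25- cells.

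**Figure D3:**
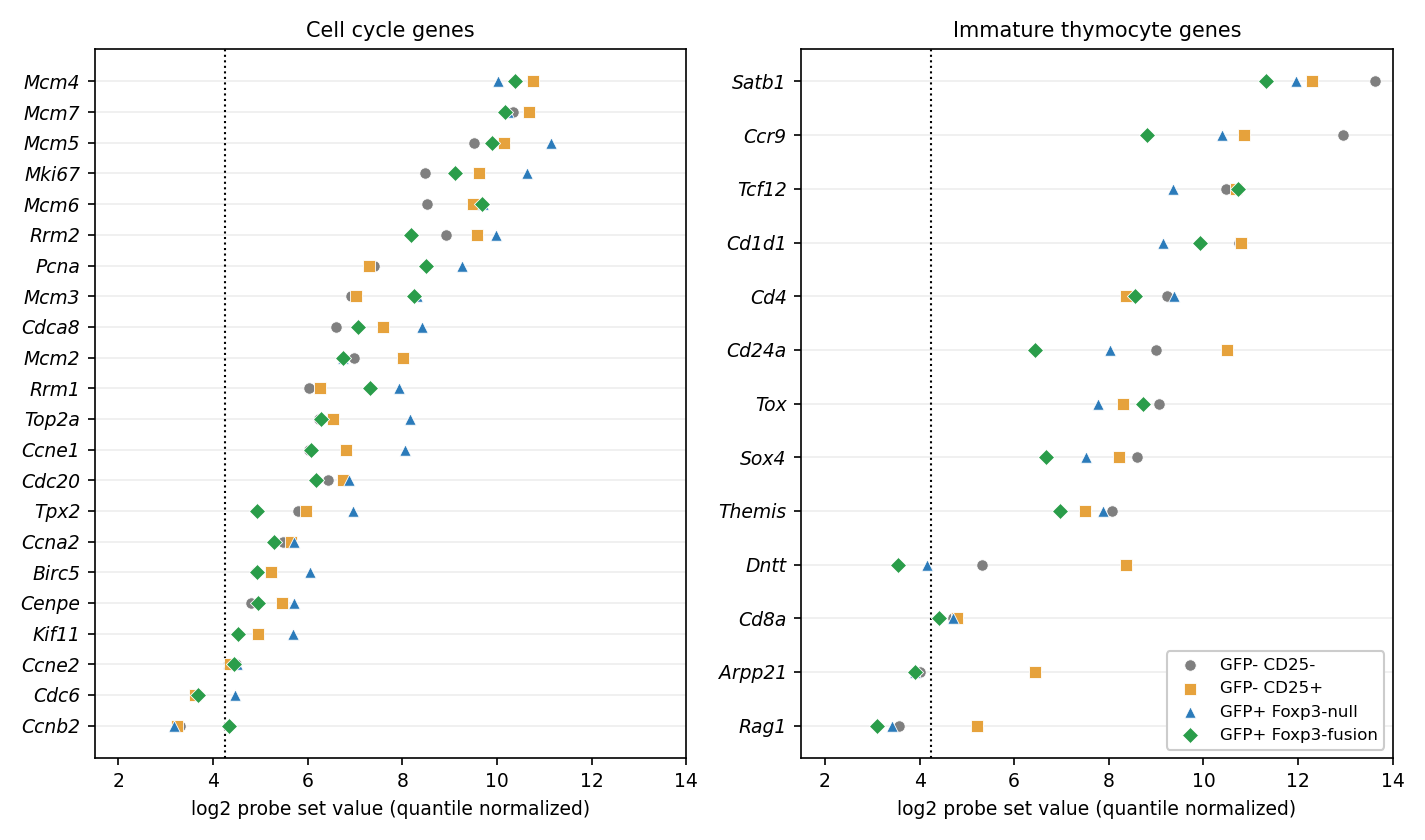
Quantile-normalized log2 probe set values of cell cycle genes (left) and immature thymocyte genes (right) on the 4 arrays, 1 symbol per array; the dotted line is the floor of 4.25 log2. Foxp3-null cells had the highest value for Mki67 (10.62, against 8.48, 9.63 and 9.11 in GFP- CD25-, GFP- CD25+ and Foxp3-fusion cells), and GFP- CD25+ cells had the highest value for Dntt (8.37).

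Foxp3-fusion cells were also compared with GFP- CD25+ cells, which carry CD25 without GFP-Foxp3. Foxp3 led at no less than 23.9-fold, followed by Fgl2 at no less than 21.9-fold and Ncoa4 at 14.9-fold. Cd48 was 13.7-fold higher, Socs2 12.8-fold, and H2-M3, a class Ib histocompatibility gene, at least 12.7-fold. Ccndbp1 was at least 12.8-fold higher, Ostm1 12.3-fold, P4ha1 at least 12.2-fold and Tmbim6 12.0-fold. Psg28 was 20.05-fold lower, Marcks 19.0-fold, Dntt at least 17.4-fold and Cd24a 16.4-fold. Pde3b was 14.3-fold lower, Ccdc22 11.7-fold, Rapgef3 at least 11.02-fold, Pou2af1 at least 8.67-fold, Mpzl2 at least 7.75-fold and Marcksl1 7.63-fold.

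Among regulatory T cell genes, 21 of 27 were at least 2-fold higher in Foxp3-fusion than in GFP- CD25+ cells and 0 lower, with a median of 1.46 (random lists, -0.34 to 0.27). Gpr83 was 7.34-fold higher and Il2rb 7.02-fold. Mature single-positive thymocyte genes had a median of 1.14 (random lists, -0.56 to 0.41), with 7 of 13 at least 2-fold higher, H2-D1 by 8.63-fold, and immature thymocyte genes one of -0.96 (random lists, -0.50 to 0.37), with 5 of 13 at least 2-fold lower. Interferon-stimulated genes had a median of 0.72 (random lists, -0.42 to 0.32), with 7 of 19 at least 2-fold higher and 0 lower, and Gbp3 reached 7.83-fold. Other list medians outside their random ranges were 1.059 for ribosomal proteins, 0.84 for trafficking and adhesion, 0.68 for the NF-kappaB and TNF receptor family, and 0.58 for the T cell receptor response. In this comparison 937 genes were at least 2-fold higher and 661 lower of 8041 measured, or 58.6% higher. The deposited scale gave 1700 higher and 263 lower, or 86.6% higher, with the all-gene median moving from -0.10 to 0.20. Another bright probe set went the same way for 62.0% of 316 higher genes and 66.2% of 334 lower genes, reached 2-fold that way for 29.1% and 16.5%, and 2-fold the opposite way for 9 and 25 genes. Of 96 list genes 2-fold apart, 4 were under 2-fold on the deposited scale.

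Foxp3-null cells were last compared with GFP- CD25+ cells. Gsta4 was 10.9-fold higher, Tmbim6 10.6-fold, the GTPase gene Rac2 9.42-fold and the interferon-stimulated gene Ifit1 8.66-fold. Commd4 was at least 10.4-fold higher, Rap1gds1 9.90-fold, Sema4f 8.46-fold, Foxp3 at least 8.12-fold, Nrp2 8.04-fold and Syt11 7.63-fold. Mid1 was at least 61.4-fold lower, Ecpas 18.03-fold and Dntt at least 17.4-fold. The copper transporter gene Atp7a was 14.6-fold lower, Ifngr2 12.9-fold, Cds2 11.5-fold, Rapgef3 at least 11.02-fold, Usp8 at least 10.4-fold, Zmiz1 9.75-fold and Chdh 9.53-fold.

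Regulatory T cell genes had a median of 0.54 in Foxp3-null over GFP- CD25+ cells (random lists, -0.19 to 0.38). Of 23 measured, 8 were at least 2-fold higher, such as Cd83 at 6.54-fold and Il2rb at 5.55-fold, and 1, Itgae, was 2.26-fold lower. Ctla4 was -0.05 log2 apart. Genes low in regulatory T cells had a median of 1.03 (random lists, -0.44 to 0.53), with Igfbp4 6.45-fold higher. Medians of 0.73 for the cell cycle, 0.80 for mature single-positive genes, 0.64 for ribosomal proteins, 0.57 for interferon-stimulated genes, 0.54 for trafficking and adhesion and 0.51 for the NF-kappaB and TNF receptor family lay above their random ranges, as did that of dendritic cell and macrophage markers, 0.72. That for immature thymocyte genes, -0.68, lay below. The counts were 694 genes at least 2-fold higher and 596 lower of 8079 measured, or 53.8% higher. With deposited values they were 507 and 661, or 43.4% higher, and the all-gene median went from 0.10 to 0.00. Another bright probe set went the same way for 60.5% of 220 higher genes and 56.9% of 313 lower genes, reached 2-fold that way for 15.5% and 16.0%, and 2-fold the opposite way for 21 and 19 genes. Across 3011 genes with such a probe set, its log2 difference correlated with that of the probe set used at only 0.11. In the other comparisons, in the order of the report, that correlation was 0.44, 0.26, 0.33, 0.42 and 0.25. Of 64 list genes 2-fold apart, 7 were under 2-fold on the deposited scale.

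After quantile normalization, some fixed lists showed no shift against random lists in any comparison. Over GFP- CD25- cells, Foxp3-fusion and Foxp3-null cells had medians of 0.40 and 0.31 for glycolysis, 0.33 and 0.31 for apoptosis regulators, 0.19 and 0.03 for signal attenuators, and 0.26 and 0.09 for dissociation and heat shock stress, all inside their random ranges. In Foxp3-fusion over Foxp3-null cells the signal attenuator median was 0.06, with 5 of 17 at least 2-fold higher and 2 lower. On the deposited scale it was 0.72, or 0.47 above all genes, with 7 higher and 1 lower. Single members still differed, such as Bcl2, which was 3.04-fold lower in Foxp3-fusion cells and 2.999-fold lower in Foxp3-null cells. Effector cytokine genes were mostly under the floor, with 3 of 18 measured in Foxp3-fusion over GFP- CD25- cells. Of these, Ccl5 was at least 5.15-fold higher, Lta 2.62-fold higher and Il21 at least 3.20-fold lower.

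Markers of other cells were mostly under the floor. Of 15 B cell genes only Ighm and Ms4a1 were measured. Ighm read 9.54 log2 in GFP- CD25- cells, 8.94 in GFP- CD25+ cells, 4.83 in Foxp3-null cells and 10.76 in Foxp3-fusion cells. Dendritic cell and macrophage markers had a median of 0.97 in Foxp3-null over GFP- CD25- cells (random lists, -0.30 to 0.72), with 3 of 7 measured at least 2-fold higher, C1qb by 3.87-fold, and the median was -0.00 with no floor. In Foxp3-null over GFP- CD25+ cells the median was 0.72 (random lists, -0.33 to 0.61), with 1 of 7 at least 2-fold higher. In Foxp3-fusion over GFP- CD25- cells it was -0.40, inside its random range. NK and NKT markers had a median of 0.65 in Foxp3-null over GFP- CD25- cells, above the random range of -0.14 to 0.55, which was -0.01 with no floor. In Foxp3-fusion cells it was -0.11, inside its range, and in GFP- CD25+ cells -0.70, below the range of -0.29 to 0.41. CD8 T cell markers had medians of -0.01 in Foxp3-null and -0.29 in Foxp3-fusion cells, both inside their ranges, and -0.70 in GFP- CD25+ cells, below the range of -0.32 to 0.42. With under 5 members measured, no random range was set for gamma delta T cell markers (median 0.68 in Foxp3-null over GFP- CD25- cells, 2 genes), thymic epithelium (0.20, 3 genes) or erythroid cells (0.32, 3 genes). Of the strain marker genes, Ifi202b was under the floor on all 4 arrays. For Nnt the log2 difference over GFP- CD25- cells was -0.77 in Foxp3-null cells and -0.68 in Foxp3-fusion cells. Another Nnt probe set above the floor on all 4 arrays read 7.598 in GFP- CD25- cells, 8.064 in Foxp3-null cells and 7.615 in Foxp3-fusion cells. The lower signal was thus not seen on that probe set. Silent tissue genes, which set the floor, had a median of 0.64 in Foxp3-null over GFP- CD25- cells over the 5 that passed it. In all, 50 of 113 list medians with a random range lay outside it. Independent lists of unrelated genes would give 5.65 on average. The comparisons share arrays, some lists share genes, and members of a list can vary together, so the count is no test against chance.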

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

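All tests in this part except that of X-linked genes were chosen after the result was seen.

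Of 21 named genes at least 2-fold above GFP- CD25- cells in one GFP+ population and at least 2-fold below them in the other, 6 appear in the report or its lists. These differences were not tested, since each population had 1 array. Slc35d1 was 2.91 log2 higher in Foxp3-fusion cells and lower in Foxp3-null cells (-2.05), a gap of 4.96. For Ccndbp1 the values were 1.60 and -2.07, a gap of 3.68, where the second is a bound. Ncoa4 gave 1.40 and -2.04, a gap of 3.44. Nfatc1 gave 1.07 and -1.13, a gap of 2.21. The other 2 ran the opposite way. Vat1 was at -1.15 in Foxp3-fusion cells and 2.24 in Foxp3-null cells, a gap of 3.39, and Gpd2 at -1.83 and 1.03, a gap of 2.86. On the deposited scale Gpd2 was at 0.66 in Foxp3-null cells, under 2-fold, so its opposite differences did not hold there. For Vat1 the gap was 0.00 with the median over its probe sets, so its opposite differences did not hold there either.

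Probe sets with no gene listed, which entered no comparison in the report, included 114 that were at least 2-fold higher in Foxp3-fusion than in GFP- CD25- cells and 524 that were at least 2-fold lower. Of these probe sets 2-fold apart, 17.9% were higher, against 65.1% of the probe sets with 1 or more genes listed. In Foxp3-null over GFP- CD25- cells the shares were 17.9% and 51.9%, and in GFP- CD25+ over GFP- CD25- cells 22.2% and 42.6%. In Foxp3-fusion over Foxp3-null cells the order was the reverse, 61.8% against 57.7%. Over GFP- CD25+ cells the shares were 31.5% and 62.0% in Foxp3-fusion cells and 20.6% and 50.3% in Foxp3-null cells.

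The first pattern weighed is the set of 762 genes at least 2-fold higher in Foxp3-fusion than in Foxp3-null cells. The share of X-linked genes, 4.07% (31 of 761), lay inside that of random sets (2.10 to 4.60), with 3.30% among all genes compared. It thus showed no excess of X-linked genes. Because most genes lie on other chromosomes in any case, the share cannot exclude a part played by X-linked alleles of the less backcrossed mice. Alleles on other chromosomes stay open too. Shorter amplified products on the Foxp3-null array stay open, because the genes were chosen for low signal on that array. That choice pushes their second probe sets toward higher values in GFP- CD25- than in Foxp3-null cells, and the value found, 0.14 log2 relative to all second probe sets (0.06 to 0.22, 286 genes), decides nothing. Presence of Foxp3 protein also stays open and cannot be told apart from the mice and the array, since the genes were chosen for high signal on the Foxp3-fusion array, which raises its value over GFP- CD25- cells too (0.14 log2 relative to all second probe sets, 0.04 to 0.27).

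The second pattern is the higher median of dendritic cell and macrophage markers in Foxp3-null over GFP- CD25- cells, 0.97 log2, which was -0.00 with no floor. Such cells in the sorted sample are argued against by their abundant transcripts, of which 0 of 8 were above the floor and at least 2-fold higher; Ctss alone was above the floor, at 11.86 log2 against 11.46, and Cd74 and Lyz2 lay under it on all 4 arrays. Raised dim signals on the Foxp3-null array stay open. Silent tissue genes were higher by 0.64 over the 5 measured, but the floor came from the Foxp3-null array, so genes pass it mainly by being high there and the value cannot show raised signals. No biological explanation was tested.

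The third pattern is the higher signal of cell cycle genes in Foxp3-null cells, whose median over GFP- CD25- cells was 0.40 with the median over the probe sets of each gene. Raised dim signals are argued against by the 10 bright members, whose median was 1.28 (random lists, -0.38 to 0.63). A shift of the whole array is argued against because the median less that of all genes was 0.81 to 0.92 under 3 scalings. Subtracting the median of all genes cancels such a shift, and before the floor deposited and centred values differ only by a constant per array. The 3 scalings therefore decide little about other errors of scaling, which stay open. Of the immature thymocyte transcripts Rag1, Dntt, Cd8a, Cd8b1, Arpp21 and Ptcra, 0 of 6 were above the floor and above GFP- CD25- cells, which argues against cycling thymocytes that still express Rag1, Dntt or Arpp21. The sort for CD4+ CD8- cells would itself remove CD8+ immature cells, Cd8b1 and Ptcra lay under the floor on all 4 arrays and could not register, and cycling CD4+ thymocytes without these transcripts stay open. Lack of Foxp3 protein, the strain background of these mice and effects of this 1 array remain open and were not tested.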

How the results depend on the processing

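All alternatives but the one without the sort genes come from the plan fixed at the start. No paired analysis was possible because the labels give no replicate numbers and each group had 1 array, so no array could be left out either. Genes 2-fold apart numbered 1231, 1481, 1515, 681, 1598 and 1290 in Foxp3-fusion over GFP- CD25-, Foxp3-null over GFP- CD25-, Foxp3-fusion over Foxp3-null, GFP- CD25+ over GFP- CD25-, Foxp3-fusion over GFP- CD25+ and Foxp3-null over GFP- CD25+ cells. In that order they numbered 788, 853, 885, 416, 958 and 779 with the median over the probe sets of a gene, 416, 479, 487, 189, 536 and 417 at 3-fold, and 2637, 3130, 3453, 2036, 3335 and 2874 at 1.5-fold. The totals moved by under 1.5 times with other scalings and floors, while the split between higher and lower moved on the deposited scale, as given in the report. Genes higher in both GFP+ populations over GFP- CD25- cells numbered 302, and 219 on the deposited scale and 98 at 3-fold. Those higher in Foxp3-fusion cells over both GFP- CD25- and Foxp3-null cells numbered 330, and 725 on the deposited scale and 95 at 3-fold. Genes lower in both GFP+ populations numbered 215, and 103 with the median over probe sets and 59 at 3-fold. The covariance of the differences of both GFP+ populations was 0.30, and 0.15 with no floor. A higher threshold leaves fewer genes by construction, and for the other moves the cause was not tested.

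Of 762 alternative list medians 741 moved by under 1.5-fold, 16 moved further, and 5 that lay outside their random range took the opposite sign. The T cell receptor response in Foxp3-fusion over Foxp3-null cells became -0.12 with centred arrays and -0.33 with a floor 1 log2 unit higher. T helper transcription factors in GFP- CD25+ over GFP- CD25- cells became 0.07 with the median over probe sets. Without a floor, the Foxp3-null over GFP- CD25- medians became -0.00 for dendritic cells and macrophages and -0.01 for NK and NKT cells. The limit of 1.5-fold is wider than many list medians, so the 741 need not keep their reading. In Foxp3-fusion over Foxp3-null cells the deposited scale took the cell cycle median from -0.72 to -0.16. It took that of the NF-kappaB and TNF receptor family from 0.34 to 0.92, and neither counted as moved. Gene values were run under every alternative only for the 10 largest differences in each direction per comparison. Of 807 such values, 643 stayed within 1.5-fold, 163 moved further in the same direction and 1 turned, Vat1 in Foxp3-fusion over Foxp3-null cells, at 0.00 with the median over probe sets. The cause was not tested. All 120 on the deposited scale and all 120 with centred arrays stayed within 1.5-fold. That does not extend to other genes in the report: on the deposited scale Foxp3 in Foxp3-fusion over Foxp3-null cells was 4.67-fold higher rather than 2.94-fold, and Ikzf4 turned from -0.35 to 0.24. Leaving out the sort genes, an alternative chosen after the data were seen, kept all 12 medians of the regulatory T cell and immature thymocyte lists within 1.5-fold. The floor limits differences of dim genes, many of which are bounds.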

Other observations

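Every value in this part was chosen after the results were seen. In Foxp3-fusion over GFP- CD25- cells, H2-D1 was 3.68-fold higher, H2-K1 2.42-fold, and Ifngr1, a chain of the interferon-gamma receptor, 6.23-fold. The interferon-inducible GTPase genes Gbp3, Irgm1 and Igtp were 13.1-fold, 2.27-fold and 2.19-fold higher. In Foxp3-null over GFP- CD25- cells the log2 difference was -0.04 for H2-K1 and 0.44 for Ifngr1, and Ifit1 was 3.64-fold higher. These are single genes: the list of interferon-stimulated genes had medians of 0.27 in Foxp3-fusion cells (random lists, -0.25 to 0.34; 3 of 19 at least 2-fold higher) and 0.23 in Foxp3-null cells, both inside their random ranges.

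Cish, a cytokine-signal inhibitor gene, was 8.17-fold higher in Foxp3-fusion and 8.00-fold higher in Foxp3-null cells than in GFP- CD25- cells, and 5.005-fold higher in GFP- CD25+ cells. Il2rb was at least 10.2-fold and at least 8.04-fold higher in the 2 GFP+ populations. Pim1 and Socs2 were higher in Foxp3-fusion cells by 15.8-fold and 17.5-fold, against 2.34-fold and 2.70-fold in Foxp3-null cells. No list of cytokine-signal targets was fixed or tested, and the list of signal attenuators, which holds Cish, had medians inside its random ranges in both GFP+ populations (0.19 and 0.03). The survival gene Bcl2 was lower in all 3 populations than in GFP- CD25- cells, by 3.04-fold in Foxp3-fusion, 2.999-fold in Foxp3-null and 2.38-fold in GFP- CD25+ cells.

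Mid1 read 10.59 log2 in GFP- CD25- cells, 10.18 in GFP- CD25+ cells, 9.58 in Foxp3-fusion cells and 3.83 in Foxp3-null cells. Ighm, a B cell list gene, read 4.83 in Foxp3-null cells and between 8.94 and 10.76 in the others. Both are among the 212 genes at least 2-fold lower on the Foxp3-null array than on each of the 3 others, and 154 genes were at least 2-fold higher there. Genotype, backcross, mice and array cannot be told apart for these genes.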
